A study of Litchi chinensis with 12 samples.

How the data were processed

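RNA was measured in leaves of 2 cultivars of litchi (Litchi chinensis), Guiwei and Yurong1, taken 24 h after inoculation with Peronophythora litchii, the oomycete that causes litchi downy blight, or after mock treatment with sterile water. Each of the 4 groups had 3 libraries, sequenced on an Illumina NovaSeq instrument. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to library size) with 1 column per library, per the file headers. TopHat2 2.0.12, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0 were used, per the submitters' processing notes. The roles and settings of these tools, the genome build and the annotation are not given in the sources used here, and the table holds no coordinates. The labels do not say whether the libraries of a group came from separate trees, or whether a replicate number marks a shared tree or day.

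The table held 33906 genes, of which 31896 had LITCHI identifiers and 2010 had others. Genes at 0 in every library (7242) were still listed, so no filter on low values had been applied. A description of the best protein match came with the table for all but 4198 genes, and every gene name below is that description. A description names a similar protein of another species and was not checked further.

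Low FPKM values were whole multiples of what 1 read was worth, which gave the depth. For 25409 of 25409 genes above 0 in at least 2 libraries, a whole gene length turned every value into whole reads within 0.02 of a read. The totals by which the libraries had been scaled ranged from 14996407 to 19399477 reads. On simulated reads the same step recovered 99.9% of genes exactly. Floors from a count of 0 used 3 reads over the libraries of a group and cover counting error only.

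Genes were tested when FPKM reached at least 1 in at least 3 of the 12 libraries, which left 18606 genes, 16471 of them with a description. Values were compared as log2(FPKM + 1), so fold changes understate the change of genes with low FPKM. One linear model with a mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, moderated by eBayes with a trend on mean expression. The 5 comparisons were inoculated against mock leaves in each cultivar, the difference between these responses, and Yurong1 against Guiwei in mock and in inoculated leaves. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. They measure only the spread between these libraries. No replicate block was used. These choices, the gene lists and the rule for named genes were made before the data were examined.

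The 34 gene lists were word patterns matched to the descriptions. They covered WRKY, NAC, MYB and AP2/ERF transcription factors, pathogenesis-related proteins, NLR disease resistance proteins, receptor-like kinases, calcium signalling, MAP kinases, peroxidases with NADPH oxidases, and glutathione S-transferases. Further lists covered salicylic acid, jasmonic acid, ethylene synthesis and perception, abscisic acid, auxin, phenylpropanoids with lignin, flavonoids, terpene synthesis, cytochrome P450, UDP-glycosyltransferases, photosynthesis, sugar transport with invertase, and heat shock proteins. Markers of cell types and states were cell cycle with histones, cell wall remodelling, cuticle and wax, vascular tissue, guard cells, senescence, ribosomal proteins, susceptibility genes of the MLO and DMR6 type, oomycete transcripts, and common reference genes. A gene could be in several lists. The 33 lists with at least 5 measured genes were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with the correlation estimated per list and fry were alternatives.

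The named genes were, per comparison, the 5 with the largest rise and the 5 with the largest fall among called genes with a description whose groups did not overlap. For the infection responses and their difference, the rule added up to 2 called members of each list with the smallest adjusted p, or, where no member was called, the member with the highest mean FPKM as values only. For the difference between the responses the rule did not ask for groups without overlap.

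In simulations of 18606 otherwise unchanged genes, 50 genes per size of change were shifted, some raised and others lowered. The simulated values had the same normal spread per gene in all 12 libraries, so no library stood apart in them. Of changes of 0.5, 1, 2 and 4 log2 units, limma found 12%, 64%, 90% and 100% in the Guiwei comparison, with 3 false calls. The corresponding shares were 16%, 64%, 98% and 100% with 6 false calls for the Yurong1 comparison, and 12%, 56%, 96% and 100% with 4 false calls for mock leaves. A list shifted by 0.5 was found by camera at an adjusted p of 2.25e-10, or 0.00173 with an estimated correlation, with 0 of the other lists called. The simulated genes were independent, so this does not test the preset correlation on lists whose genes move together.

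Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean FPKM of 5, rescaling to a common sum, median-of-ratios scaling, quantile normalization, eBayes without trend or with robust variance, library weights, and a fit to the compared groups alone. Others were the replicate number as a block, alone or within cultivar, an adjusted p below 0.01, a fold threshold of 1 log2 unit, and leaving out each library. Alternatives chosen after seeing the data were voom on the recovered whole reads, leaving out the heat shock list, leaving out Guiwei mock replicates 1 and 2 together, and library weights estimated gene by gene. Figures were drawn with matplotlib 3.10.9.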

Results

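The data were FPKM values of 33906 genes in 12 leaf libraries, with 3 libraries each for mock and inoculated leaves of the litchi cultivars Guiwei and Yurong1, 24 h after treatment. The totals used for scaling ranged from 14996407 to 19399477 reads, and 16728 to 17298 genes reached an FPKM of 1 per library. Cultivar separated the libraries on the first principal component, which held 58.7% of the variance. Correlations of log2 values across genes between libraries of a group were 0.958 to 0.989, except among Guiwei mock libraries, where they were 0.909 to 0.981. Guiwei mock replicate 2 stood apart. Genes of the heat shock list took 13.12% of its FPKM, against 1.41% in mock replicate 1 and 0.37% in mock replicate 3. In the other 9 libraries the share lay between 0.32% and 1.23%. The small heat shock protein gene LITCHI024905 had an FPKM of 868, 8250 and 9.03 in Guiwei mock replicates 1 to 3. Genes of the NLR and receptor kinase families can have near-identical copies whose reads cannot be placed with certainty, so values of single members are uncertain. Such copies were not looked for here.

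**Figure D1:**
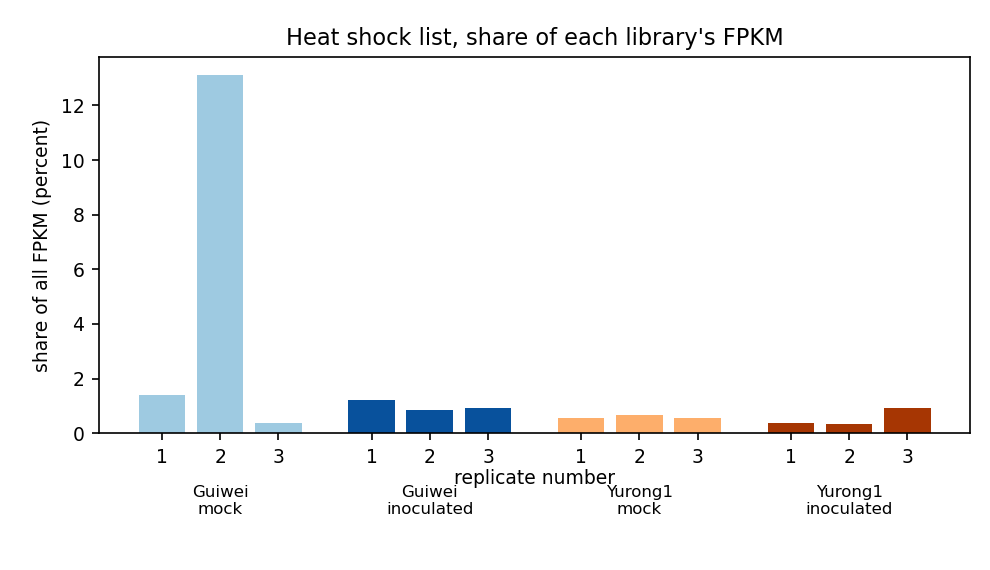
Bars give the percent of each library's summed FPKM that fell on genes of the heat shock list, for 3 libraries in each of the 4 groups. Guiwei mock replicate 2 reached 13.12%, and the other libraries lay between 0.32% and 1.41%.

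The comparison of inoculated with mock Guiwei leaves asks which genes had changed in this cultivar 24 h after the pathogen was applied. Metalloendoproteinase 1 (LITCHI017995), an extracellular-type protease, rose from a mean FPKM of 1.27 ± 0.794 to 44.1 ± 28.0 (SD, n = 3), a log2 change of 4.20 ± 0.47 (SE, limma adjusted p = 0.0067). Linalool synthase (LITCHI028401), which makes the volatile terpene alcohol linalool, rose by 4.09 ± 0.62 log2 units, from 1.47 ± 1.31 to 41.2 ± 21.1. A VQ motif protein (LITCHI028392) rose by 3.55 ± 0.49, and the AAA-ATPase ASD (LITCHI019572) by 3.66 ± 0.71. The glycerophosphodiester phosphodiesterase GDPD1 (LITCHI020795), of an enzyme class that acts in lipid turnover, fell by 2.45 ± 0.40, and the sugar transporter ERD6-like 16 (LITCHI014613) fell by 1.85 ± 0.33. Also named by the rule were LITCHI000038, with a rise of 3.64, and LITCHI020557 (−2.28), LITCHI010987 (−2.09) and the 21 kDa protein gene LITCHI009127 (−1.85).

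Among Guiwei genes grouped by list, 5 of 57 measured pathogenesis-related genes rose and 0 fell, or 11 and 1 adjusted over the list alone. Endochitinase EP3 (LITCHI015508), of a family that cleaves chitin, rose by 2.45 (adjusted p = 0.0197), and the pathogenesis-related protein STH-2 (LITCHI014417) by 1.24. Of 264 receptor-like kinases 10 rose and 0 fell, or 48 and 3 adjusted over the list alone. They included a GSO2-like leucine-rich repeat receptor kinase (LITCHI017301) at 1.66 ± 0.15 and MDIS1-interacting receptor like kinase 2 (LITCHI002890) at 1.85. Both called peroxidases of 29 measured rose, cationic peroxidase 1 (LITCHI018055) by 2.07 and peroxidase 68 (LITCHI027458) by 2.78, with 5 rising over the list alone. A pair of cinnamoyl-CoA reductases, enzymes of the lignin branch, rose by 1.10 (LITCHI019938) and 0.76 (LITCHI004425) among 60 phenylpropanoid genes, of which 6 rose and 2 fell over the list alone. Cell wall invertase (LITCHI030108), which splits sucrose outside the cell, rose by 2.11, while ERD6-like 16 fell in the same list of 32 genes. Single members rose among 44 AP2/ERF factors (ERF114, LITCHI020245, 1.84), 38 NAC factors (NAC100, LITCHI019504, 1.04), 197 NLR proteins (LITCHI013592, 0.91), 22 terpene genes (linalool synthase) and 74 cytochromes P450 (724B1, LITCHI020639, 0.88). Single members fell among 62 cell cycle genes (cyclin-A2-1, LITCHI017079, −1.13), 69 cell wall genes (a xyloglucan endotransglycosylase, LITCHI024593, −0.97) and 9 susceptibility genes (MLO-like 12, LITCHI029123, −0.67). In the remaining 20 tested lists limma called 0 members in Guiwei, while 3120 of all genes had an unadjusted p below 0.05. These counts moved with single libraries. Without Guiwei mock replicate 1, 0 pathogenesis-related genes and 5 receptor-like kinases rose, and without inoculated replicate 3, 4 and 21. Without mock replicate 2 they were 3 and 6, with 0 peroxidases and 2 flavonoid genes higher, and without mock replicate 3, 7 heat shock genes were lower.

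As groups against all other genes, camera called 4 lists higher and 2 lower in Guiwei. The receptor-like kinases lay higher (median log2 change 0.26, 191 of 264 positive, adjusted p = 1.72e-06), as did WRKY factors (0.41, 26 of 30 positive, 0.00693), NLR proteins (0.12, 0.0297) and calcium signalling (0.24, 0.0297). Cell cycle genes (−0.16, 0.0128) and heat shock proteins (−0.31, 0.0297) lay lower. For each of the 6 the adjusted p was 0.846 with an estimated correlation, and fry called 0 lists. No WRKY member was called, and the most abundant, WRKY70 (LITCHI027573), had a change of 0.32 ± 0.33 (adjusted p = 0.671). The heat shock list moved with Guiwei mock replicate 2, without which its median was 0.15 and its adjusted p 0.193. Its call also ended without inoculated replicate 3. Without mock replicate 2 the calls of calcium signalling and cell cycle genes ended too, and the medians were 0.13 for receptor-like kinases, 0.05 for NLR proteins and −0.10 for pathogenesis-related proteins (0.10 with all libraries). Without Guiwei mock replicate 1 or inoculated replicate 2, those of WRKY, NLR and calcium genes ended, while the receptor-like kinases stayed called without any of the 12 libraries.

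In all, limma called 176 genes in Guiwei (130 higher, 46 lower), 91 of the higher and 28 of the lower by at least 2-fold. The 3 libraries of each group did not overlap for 20% of genes, where chance gives 10%. The count was 43 without mock replicate 1, 40 without inoculated replicate 1, 72 without inoculated replicate 2 and between 86 and 105 without any Yurong1 library. Fitted to the Guiwei libraries alone it was 3. Of the 26 calls named here 6 stayed in all 12 fits that left out a library, those of LITCHI017995, LITCHI020557, LITCHI017301, LITCHI002890, LITCHI030108 and LITCHI017079. The calls of LITCHI019504, LITCHI013592 and LITCHI020639 stayed in only 1 of the 12 fits. Those of LITCHI019572, LITCHI009127, LITCHI004425, LITCHI024593 and LITCHI029123 stayed in 2.

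The same comparison in Yurong1 asks which genes had changed in the second cultivar. A homolog of late blight resistance protein R1B-8 (LITCHI028104) rose from a mean FPKM of 22.2 ± 29.7 to 365 ± 159 (SD, n = 3), a log2 change of 4.86 ± 1.09 (SE, limma adjusted p = 0.0391). Metalloendoproteinase 1 (LITCHI017995) rose by 4.30 ± 0.47, AAA-ATPase ASD (LITCHI019572) by 3.92, the VQ motif protein (LITCHI028392) by 3.91 and the pathogenesis-related gene PR2-2 (LITCHI014384) by 3.68. Metallothionein type 2 (LITCHI024891), a metal-binding protein, fell from 257 ± 22.1 to 53.2 ± 10.4, a log2 change of −2.26 ± 0.26 (adjusted p = 0.00185). Acid phosphatase 1 (LITCHI030447) fell by 2.86 ± 0.54. A CRT/DRE-binding factor (LITCHI009273, −2.35), of a family that acts in the cold response, MLP-like protein 28 (LITCHI005803, −2.12) and LITCHI012894 (−2.14) fell as well.

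Among Yurong1 genes grouped by list, 8 of 57 pathogenesis-related genes rose and 4 fell, or 13 and 16 adjusted over the list alone. STH-2 (LITCHI014417) rose by 1.97 and pathogenesis-related protein P2 (LITCHI003626) by 2.86 ± 0.34 (adjusted p = 0.00203), while the median of the list was −0.18 and its mean 0.09. More rose than fell only in part of the fits: 10 rose and 10 fell with median-of-ratios or quantile scaling, 11 and 15 without Guiwei mock replicate 2, and 3 and 0 without Yurong1 inoculated replicate 1. Of 264 receptor-like kinases 19 rose and 3 fell, or 26 and 10 over the list alone. With either scaling 23 rose and 8 fell, without Guiwei mock replicate 2 these were 27 and 15, and without Yurong1 inoculated replicate 1 only 8 rose. The GSO2-like kinase (LITCHI017301) rose by 2.03 ± 0.15 and receptor-like kinase At4g00960 (LITCHI029419) by 1.71. Cytochromes P450 split into 6 that rose, such as 71B37 (LITCHI004812, 2.49), and 3 that fell, such as LITCHI010877 (−1.72), of 74, or 11 and 11 without Guiwei mock replicate 2. Of 29 peroxidases 3 rose and 0 fell, among them cationic peroxidase 1 (LITCHI018055, 2.59) and peroxidase 2 (LITCHI024186, 0.80). Of 197 NLR proteins 2 rose, R1B-8 among them, and the R1B-16 homolog (LITCHI010299) fell by 1.29. Glutathione S-transferase U44 (LITCHI025921) rose by 0.85 among 12 members, of which 5 rose and 1 fell over the list alone. Cell wall invertase (LITCHI030108) rose by 2.01, and the sugar transporter SWEET3 (LITCHI009513) fell by 0.72. ERF114 (LITCHI020245) rose by 2.38. Of 51 MYB factors 3 rose, LITCHI023435 (0.91) and LITCHI023106 (0.81) among them, and 1 fell. Both called NAC factors fell, LITCHI008829 (−0.81) and LITCHI007494 (−1.06). The smaller counts moved with single libraries too. Only 1 peroxidase, 0 MYB factors and 0 NLR proteins rose without Guiwei mock replicate 1. Without Guiwei inoculated replicate 2, 6 peroxidases and 6 NLR proteins rose, and without Guiwei mock replicate 2, 2 peroxidases and 5 NAC factors fell and 4 glutathione S-transferases and 5 AP2/ERF factors rose. Without Yurong1 mock replicate 2, 1 cytochrome P450 rose and 0 NAC factors fell, and without Yurong1 inoculated replicate 1, 0 glutathione S-transferases rose. The calls of LITCHI023435 and LITCHI023106 stayed in 5 and 4 of 12 such fits.

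Among the hormone lists in Yurong1, both called jasmonic acid genes of 20 fell, allene oxide cyclase 3 (LITCHI019276), an enzyme of jasmonate synthesis, at −1.68 ± 0.26 and TIFY 9 (LITCHI004576), of the family of jasmonate signalling repressors, at −1.06. Of 16 salicylic acid genes 1 rose, salicylic acid-binding protein 2 (LITCHI006766, 1.61), and 2 fell, among them NIM1-INTERACTING 1 (LITCHI026632, −1.38), a partner of the salicylic acid regulator NIM1. EIN3-binding F-box protein 1 (LITCHI016994), a negative regulator in ethylene signalling, rose by 1.16 among 15 ethylene genes. Of 62 auxin genes GH3.17 (LITCHI026265, −0.95) and auxin efflux carrier component 8 (LITCHI017892, −0.89) fell. Both called calcium genes of 63 fell, calmodulin-like protein 5 (LITCHI015895, −1.81) and CML27 (LITCHI023087, −1.70). In the terpene list of 22, 2 genes described as terpene synthase 10 fell, LITCHI028835 (−1.76 ± 0.13, from a mean FPKM of 3.25 to 0.254) and LITCHI028829 (−1.94). Another gene of that description, LITCHI028830, had a mean FPKM of 0.0184 over the Yurong1 libraries and no room to fall. Linalool synthase (LITCHI028401) rose by 2.82. Laccase-17 (LITCHI024798), of a family that polymerises lignin, fell by 1.16 among 60 phenylpropanoid genes, of which 6 rose and 5 fell without Guiwei mock replicate 2. Of 62 UDP-glycosyltransferases 83A1 (LITCHI019399) fell by 1.24 with 1 other, and 43-like (LITCHI028436) rose by 0.73. With all libraries limma called 0 members in either cultivar among WRKY factors, 26 MAP kinases, 10 abscisic acid, 34 flavonoid, 30 photosynthesis and 5 senescence genes, with 3120 and 3594 of all genes at an unadjusted p below 0.05. Without Guiwei mock replicate 2, Yurong1 had 6 higher and 1 lower flavonoid genes, 1 and 1 WRKY factors, 2 lower MAP kinases, 2 lower abscisic acid genes, 4 lower jasmonic acid genes, 5 lower calcium genes and 6 lower auxin genes. Lower genes numbered 0 for jasmonic acid without Yurong1 inoculated replicate 1, for auxin without Yurong1 mock replicate 3 and for calcium without Yurong1 mock replicate 2. The oomycete list matched 1 gene, which did not pass the filter, so the amount of pathogen in the leaves was not measured here.

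As groups, camera called 3 lists higher and 3 lower in Yurong1. Ribosomal proteins lay higher (median 0.37, 137 of 147 positive, adjusted p = 4.14e-15, and 0.766 with an estimated correlation). Of these 4 were called, all higher, or 14 over the list alone, such as 60S L21-2 (LITCHI019077, 0.83) and 40S S3a (LITCHI019431, 0.60). Cuticle and wax genes (0.45, adjusted p = 0.00388, and 0.732 with an estimated correlation) rose in 3 of 14 cases, or 5 over the list alone, with 1 without Guiwei mock replicate 1 and 6 without Guiwei mock replicate 2. 3-ketoacyl-CoA synthase 11 (LITCHI014914), which elongates fatty acids, rose by 2.61 ± 0.25 from a mean FPKM of 0.251 to 6.88, and synthase 10-like (LITCHI017426) by 0.93 from 203 to 391. Glutathione S-transferases lay higher (0.46, adjusted p = 0.00939, and 0.697 with an estimated correlation). Fry, which asks whether a set moves one way and does not compare it with other genes, gave an adjusted p of 0.0397 for cuticle genes and 0.0144 for glutathione S-transferases. Cell wall genes lay lower (−0.32, adjusted p = 5.37e-05, and 0.732 with an estimated correlation), with 1 of 69 called, cellulose synthase-like D3 (LITCHI020486, −0.80), and 13 lower over the list alone. With median-of-ratios scaling 9 cell wall genes were called lower and 15 ribosomal proteins higher, without Guiwei mock replicate 2 these were 16 and 29, and without Guiwei mock replicate 1 both were 0. Cell cycle genes (−0.15, adjusted p = 0.00939, and 0.829 with an estimated correlation) and common reference genes (−0.15, 0.0313, and 0.929 with an estimated correlation) also lay lower, but neither call stayed without inoculated replicate 1, nor that of reference genes without inoculated replicate 3 (adjusted p up to 0.0752 and 0.0655). Cyclin-A2-1 (LITCHI017079) fell by 0.82, and single falls in other lists were those of MLO-like 12 (LITCHI029123, −0.81), the stomatal lineage protein BASL (LITCHI023313, −1.10) and the vascular list's fasciclin-like arabinogalactan protein 17 (LITCHI019007, −0.58). A class I small heat shock protein (LITCHI018305, −1.36) and a tubulin alpha chain of the reference list (LITCHI007136, −0.95) also fell. A gamma-tubulin complex component (LITCHI000241), in the same list, rose by 0.88.

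In all, limma called 586 genes in Yurong1 (280 higher, 306 lower), 164 of the higher and 156 of the lower by at least 2-fold. Groups did not overlap for 31.7% of genes, against 10% by chance. The count was 113 without inoculated replicate 1, 208 without inoculated replicate 2, 223 and 134 without mock replicates 2 and 3, 387 without Guiwei mock replicate 1, 359 without Guiwei inoculated replicate 1, and 1815 without Guiwei mock replicate 2, which enters through the shared estimate of the spread. Fitted to the Yurong1 libraries alone it was 1243. Of 53 named calls 17 stayed in all 12 fits that left out a library, and R1B-8 did in 5 of the 12.

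**Figure D2:**
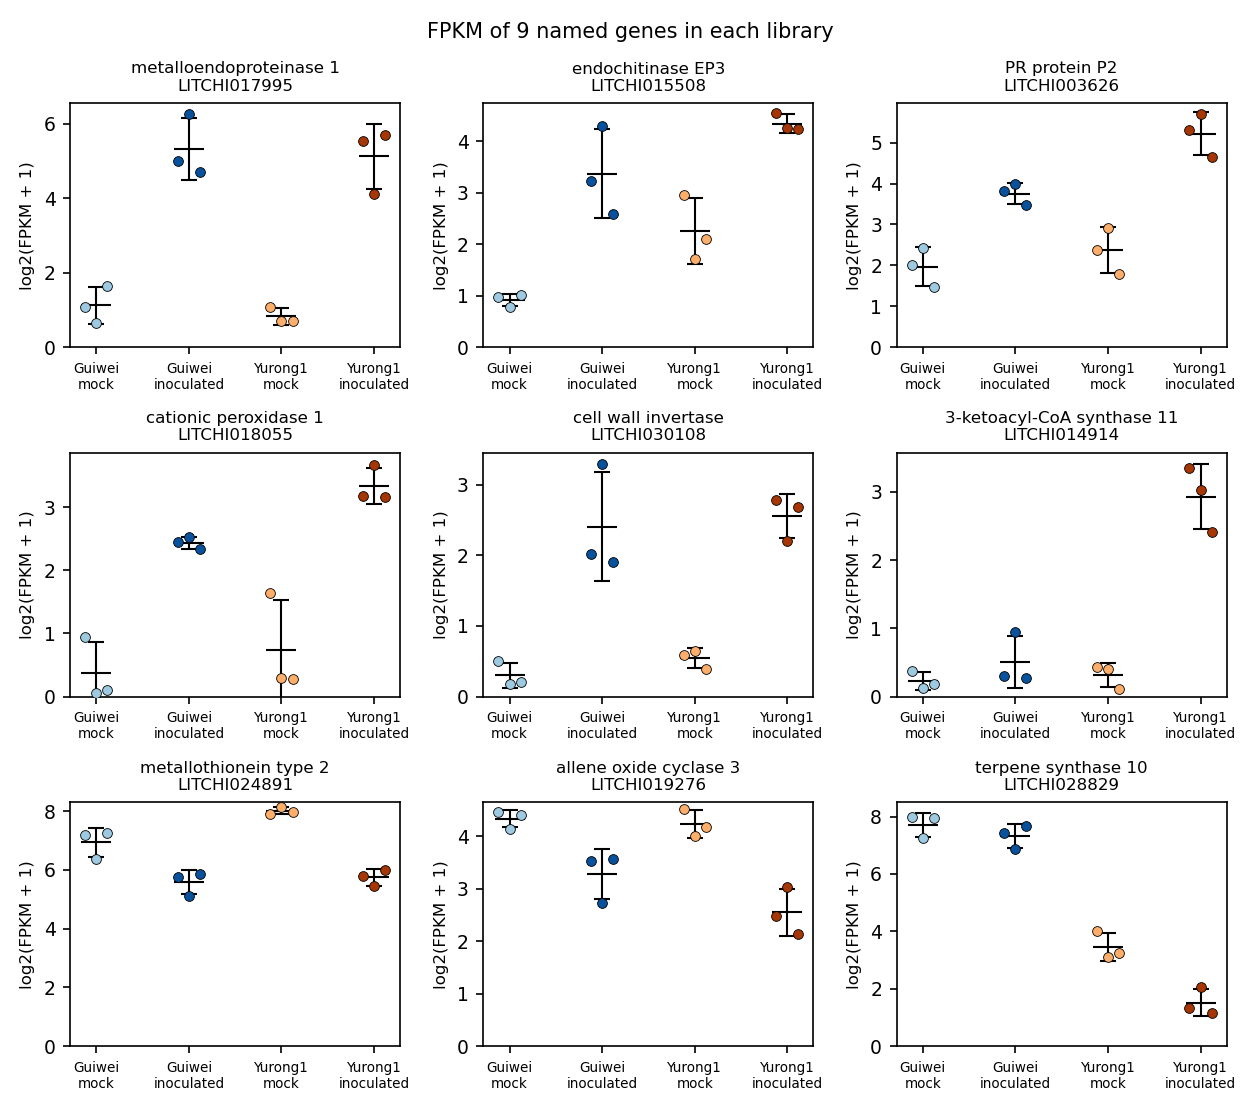
Dots give log2(FPKM + 1) of 9 named genes in each of 3 libraries per group, and horizontal marks and bars the mean ± SD. Metalloendoproteinase 1 rose in both cultivars, from a mean FPKM of 1.27 to 44.1 in Guiwei and from 0.795 to 37.9 in Yurong1.

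**Figure D3:**
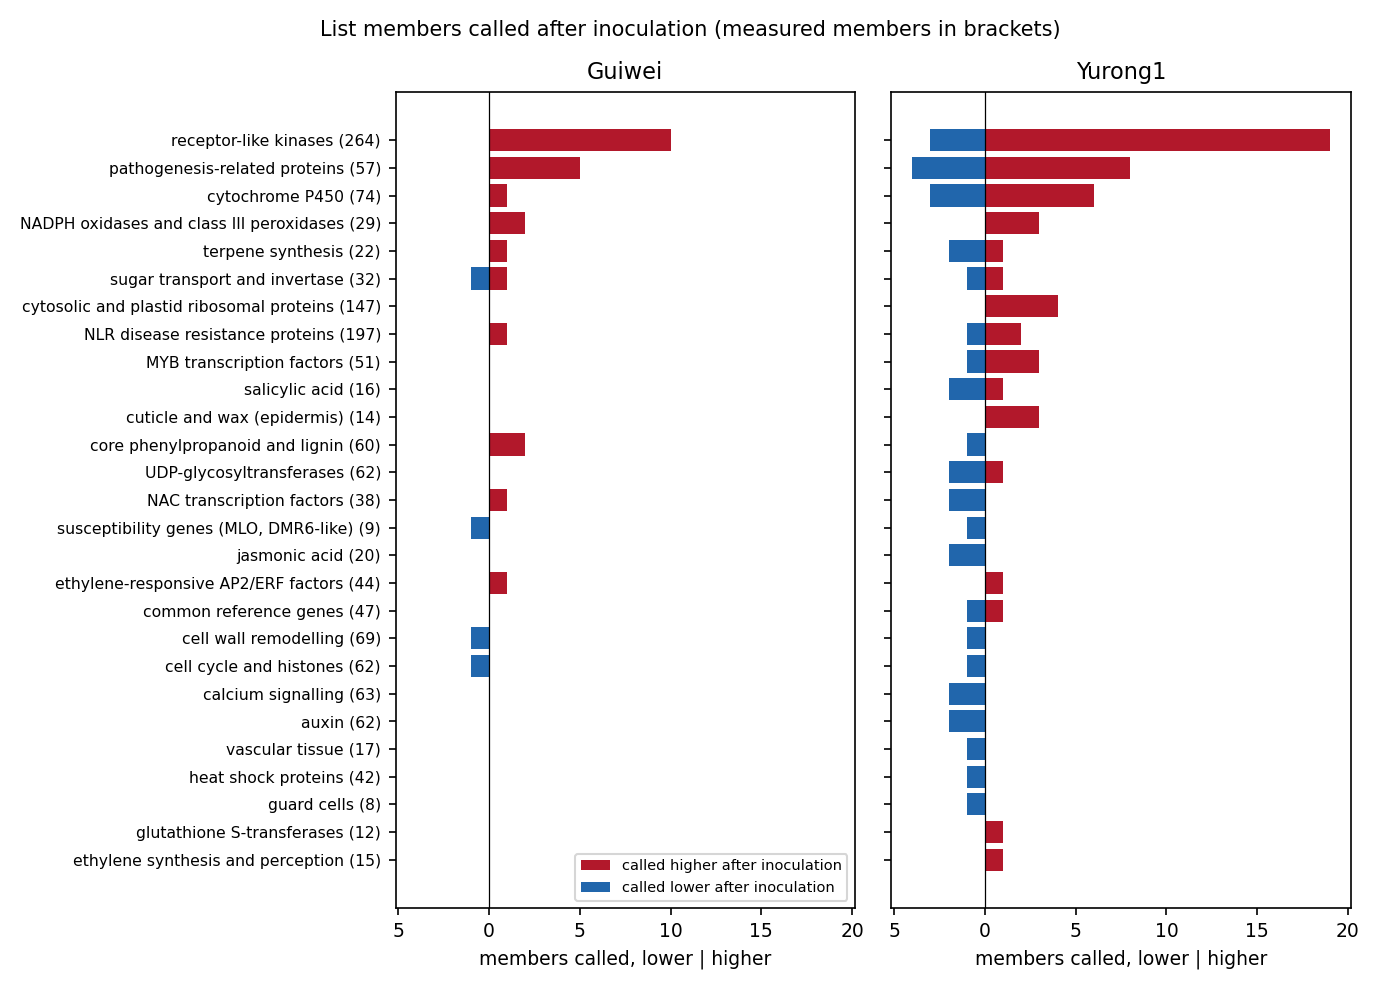
Bars to the right and left count list members called higher and lower after inoculation in each cultivar, for lists with any call; measured members stand in brackets. Receptor-like kinases held the most, with 10 higher in Guiwei, and 19 higher and 3 lower in Yurong1.

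Whether the cultivars responded differently was tested as the difference between their responses. Across the 18606 genes, which are not independent replicates, the changes in the 2 cultivars correlated with a Pearson r of 0.40 and a Spearman rho of 0.25, from comparisons that share no library. The cultivars shared 62 genes called higher, where independent lists would share 1.96, and 11 called lower, where they would share 0.76. Both comparisons use the same estimate of the spread per gene, so the lists are not independent and these baselines may be too low. Limma called 0 genes in opposite directions and voom 1, and of 965 genes at an unadjusted limma p below 0.05 in both cultivars 110 went in opposite directions. Shared higher genes numbered 22 without Guiwei mock replicate 1, Guiwei inoculated replicate 1 or Yurong1 inoculated replicate 1, 25 without Yurong1 mock replicate 3, and 34 to 39 without Guiwei inoculated replicate 2 or any of the other 4 Yurong1 libraries. Shared lower genes ranged from 1 without Guiwei inoculated replicate 1 to 64 without Guiwei mock replicate 2, where 4 genes were opposite. Of the genes called in Guiwei 85.2% changed with the same sign in Yurong1.

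The test of the difference called 3 genes. The gibberellin-regulated protein GAST1 (LITCHI008721) fell in Yurong1 from a mean FPKM of 20.3 ± 3.63 to 7.05 ± 0.687. In Guiwei it went from 21.2 ± 3.31 to 28.0 ± 2.89, a difference of −1.78 ± 0.21 (SE, limma adjusted p = 0.0316). This call stayed in 5 of the 12 fits that left out a library. Terpene synthase 10 (LITCHI028835) had a difference of −1.71 ± 0.19 (adjusted p = 0.0303), and its mean FPKM in Guiwei was 0.0554 in mock and 0.0188 in inoculated leaves. At that level it had no room to fall in Guiwei, so its difference restates the fall in Yurong1 and does not show a different response. LITCHI028829, with the same description, had a difference of −1.54 ± 0.456 that was not called (adjusted p = 0.283). The undescribed gene Novel00045, chosen after its values were seen, had a difference of 3.36 ± 0.41 (adjusted p = 0.0316). It rose from 0.935 ± 0.262 to 52.2 ± 3.49 in Yurong1 and from 0 to 1.95 ± 1.43 in Guiwei, at least 12-fold over a floor of 3 reads in the group (log2 changes 4.79 ± 0.29 and 1.43 ± 0.29). With Guiwei mock leaves at 0, the difference is one of log2(FPKM + 1) and does not rank the folds of the cultivars. Voom on whole reads called 0 genes, while median-of-ratios scaling, quantile normalization and library weights gene by gene each called more than 3. An unadjusted limma p below 0.05 was reached by 2246 genes. Counts were 0 without Guiwei mock replicate 1, Guiwei inoculated replicate 1, Yurong1 mock replicate 2 or 3, or Yurong1 inoculated replicate 1, and 5 to 12 without Guiwei mock replicate 2 or 3, Guiwei inoculated replicate 2 or Yurong1 inoculated replicate 3.

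Lists were compared between the responses too, and only camera at its preset correlation called any. This comparison uses the same libraries as the response of each cultivar, so its list results are not independent of those above. Camera called cuticle and wax genes (median difference 0.43, 12 of 14 positive, adjusted p = 0.00176) and ribosomal proteins (0.22, 124 of 147, 8.47e-07) as higher in the Yurong1 response. It called receptor-like kinases (−0.19), jasmonic acid (−0.38, 0 of 20 positive), auxin (−0.19) and cell wall genes (−0.30) as lower, each at an adjusted p of 0.0194, and terpene (−0.22, 0.0234) and calcium genes (−0.20, 0.0414) likewise. The adjusted p was 0.853 for each with an estimated correlation, and fry called 0 lists. Within lists 0 members were called, apart from LITCHI028835. Without Guiwei mock replicate 2 the calls for receptor-like kinases, calcium, jasmonic acid and terpene genes ended, with medians of −0.06, −0.08, −0.17 and −0.06. Calls also ended without inoculated replicate 2 of either cultivar (receptor-like kinases, calcium), Yurong1 inoculated replicate 3 (receptor-like kinases), Guiwei mock replicate 1 (calcium), Yurong1 mock replicate 3 (calcium, jasmonic acid) and Yurong1 mock replicate 1 (terpene). Cuticle, ribosomal, auxin and cell wall genes stayed called without any of the 12 libraries, but without Guiwei mock replicate 2 the medians were −0.09 for auxin, −0.16 for cell wall and 0.33 for ribosomal genes.

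**Figure D4:**
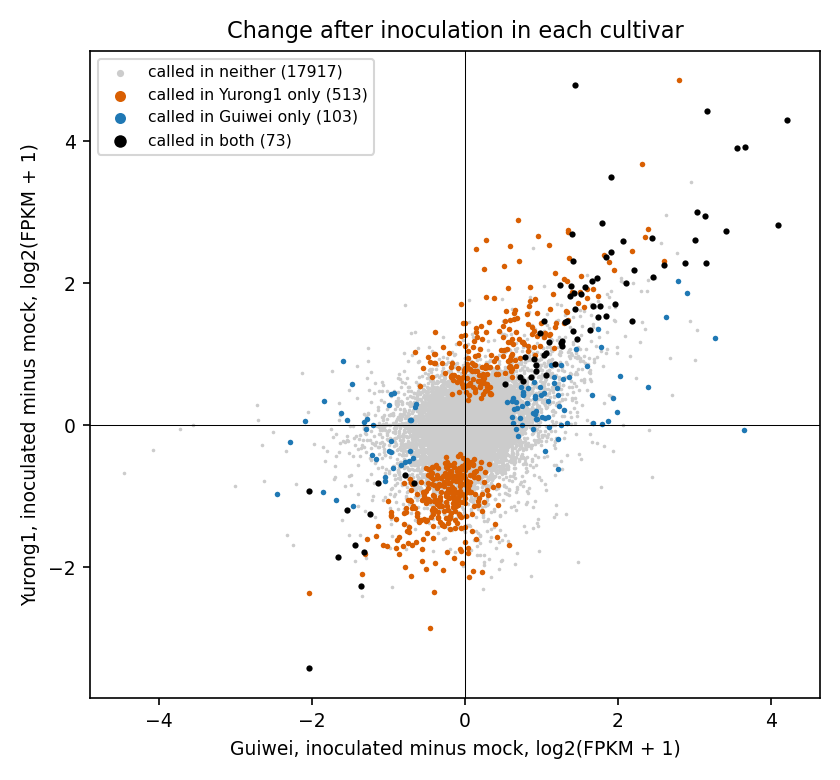
Each dot is a gene, with its change after inoculation in Guiwei (horizontal) and Yurong1 (vertical) as differences of log2(FPKM + 1), coloured by the cultivars in which limma called it. Of the genes called in both cultivars, 62 were higher in both, 11 lower in both and 0 opposite.

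The comparison of mock leaves asks how the cultivars differed without the pathogen. Differences of presence and absence led the genes higher in Yurong1. Alpha-galactosidase 3 (LITCHI000574), of a family that releases galactose from sugars, had a mean FPKM of 310 ± 32.9 (SD, n = 3) in Yurong1 and 0 in Guiwei, at least 1400-fold higher by the floor of 3 reads (limma log2 difference 8.27 ± 0.12, adjusted p = 7.19e-12). Its neighbours by identifier, LITCHI000573 and the methyltransferase PMT3 (LITCHI000572), were higher by 6.36 and 6.34. LITCHI017946, at 57.9 against 0, was at least 250-fold higher, and the resistance protein At4g27220 (LITCHI017949) was higher by 5.59 ± 0.15. Sodium/hydrogen exchanger 2 (LITCHI000233) was at 0 in Yurong1 and at 56.1 ± 8.97 in Guiwei, at least 320-fold lower in Yurong1. DMR6-LIKE OXYGENASE 1 (LITCHI001700), of a family that hydroxylates salicylic acid, lay lower in Yurong1, at −5.07 ± 0.56 (adjusted p = 4.92e-05).

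Other genes named as lower in Yurong1 mock leaves moved with Guiwei mock replicates 1 and 2. A chloroplast small heat shock protein (LITCHI012165) had an FPKM of 540, 6150 and 10.2 in the 3 Guiwei mock libraries and a difference of −7.17 ± 1.62, which ranged from −9.62 to −5.07 when a library was left out. The differences of a putative cell wall protein (LITCHI021094) and LITCHI012033 were −6.21 (adjusted p = 0.00228) and −5.59 ± 1.77, and the latter call ended in 5 of 12 such fits. In all, limma called 6033 genes (3192 higher and 2841 lower in Yurong1, 1533 and 1167 by at least 2-fold), and groups did not overlap for 46.5% of genes, against 10% by chance.

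Camera placed 3 lists apart in mock leaves. NLR proteins lay higher in Yurong1 (79 of 197 members higher, 45 lower, median 0.27, adjusted p = 0.0351), as did receptor-like kinases (76 higher, 23 lower, 0.32, 0.0232), and cuticle and wax genes lay lower (0 of 14 higher, 6 lower, −0.74, 0.0351). The adjusted p was 0.874 for each with an estimated correlation, and adjusted over the list alone the counts were 84 and 48, 80 and 24, and 0 and 7. Without Guiwei mock replicate 2 the median of receptor-like kinases was 0.18, with 59 higher and 22 lower. The call for NLR proteins ended without Guiwei mock replicate 1, and those for NLR proteins and cuticle genes without Yurong1 mock replicate 3. Fry called 10 lists. The mock libraries compared here are also the controls of the infection responses and of their difference. The places of the same lists in those comparisons are therefore not independent of the ones here. Limma called 32.4% of all genes tested in mock leaves, so called members alone do not set a list apart. Lists without a camera call held such members too, with 14 higher and 4 lower NAC factors, 9 higher and 1 lower vascular genes of 17, and 10 higher and 19 lower cytochromes P450. Of these, 9 NAC factors were higher without Guiwei mock replicate 1, 6 cytochromes P450 without Yurong1 mock replicate 2, and 4 vascular genes without Yurong1 mock replicate 3, where 53 receptor-like kinases were higher and 14 lower.

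The comparison of inoculated leaves asks how the cultivars differed 24 h after inoculation. LITCHI000574, LITCHI000572 and LITCHI000573 were again higher in Yurong1, by 7.61, 6.32 and 5.81 (limma), with amidase At4g34880 (LITCHI001985) at 5.73 ± 0.14 and LITCHI017946 at least 210-fold higher. Terpene synthase 10 (LITCHI028829) was lower, at 1.98 ± 1.05 against 164 ± 44.9 FPKM in Guiwei (−5.81 ± 0.32, adjusted p = 1.79e-07). LITCHI000038 was lower at −6.70 ± 0.64, and LITCHI000233 at least 320-fold lower. Anion transporter 6 (LITCHI002740), at 0 in inoculated Yurong1 leaves, was at least 560-fold lower, and the resistance protein NBS49 (LITCHI002738) had a difference of −5.17. The 10 named calls stayed in all 12 fits that left out a library.

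In all, limma called 4284 genes between inoculated leaves (2132 higher and 2152 lower in Yurong1), and groups did not overlap for 42.1% of genes, against 10% by chance. NLR proteins held 71 higher and 48 lower members of 197. Of 12 glutathione S-transferases 6 were higher and 0 lower, and of 22 terpene genes 3 were higher and 9 lower. Camera called 0 lists, with a smallest adjusted p of 0.947 with an estimated correlation, and fry called 5, among them glutathione S-transferases (adjusted p = 0.000121), AP2/ERF factors, NLR proteins and vascular genes (0.0279 each) and terpene genes (0.0458).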

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

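The tests of the inoculated swap and of spread in the called counts, and the test of neighbouring identifiers, were chosen after the result was seen. The test of the difference between the infection responses of the 2 cultivars called 3 genes, and 8 gene lists with camera at its preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.853 each), and fry called 0. The gibberellin-regulated GAST1 (LITCHI008721, −1.78 log2 units) fell in Yurong1 and was not called in Guiwei. Terpene synthase 10 (LITCHI028835, −1.71) fell in Yurong1, but at a mean FPKM of 0.0554 in Guiwei mock leaves it had no room to fall there, so no different response is shown. The undescribed gene Novel00045 had a difference of 3.36 on the log2(FPKM + 1) scale, but with Guiwei mock leaves at 0 its rise there is only a lower bound (at least 12-fold over a floor of 3 reads in the group), so the folds cannot be ranked. Lower in the Yurong1 response were receptor-like kinases, jasmonic acid, auxin and cell wall genes (camera adjusted p = 0.0194 each), terpene (0.0234) and calcium genes (0.0414), and higher were cuticle genes (0.00176) and ribosomal proteins (8.47e-07). Leaving out Guiwei mock replicate 2 ended the calls of receptor-like kinases, jasmonic acid, terpene and calcium genes, with medians of −0.06, −0.17, −0.06 and −0.08. Of 100 splits of the libraries, 2 called at least as many genes as the 3 called here, the real split included, a share under 0.05, although the highest of the others also called 3. Splits that mix mock and inoculated leaves add the response shared by the cultivars to the spread, and only 8 of the 100 called any gene. The share therefore cannot decide whether the 3 calls arose by chance. The count was 0 without any 1 of 5 libraries and with voom, a replicate block or rescaling to a common sum. It reached 12 without another library, and was also larger with median-of-ratios scaling or quantile normalization.

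For the comparisons of 2 groups the 10 possible splits were too few for a share under 0.05, and 1 split, the real one, reached the real count in each. The real and highest other counts were 176 and 0 in Guiwei and 586 and 0 in Yurong1 after inoculation. Between the cultivars they were 6033 and 0 in mock and 4284 and 1 in inoculated leaves. Every other split mixes the 2 groups and adds their difference to the spread. Low counts follow from that, so the contrast with the real counts does not support the calls.

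In Guiwei mock replicate 2, with 13.12% of its FPKM on the heat shock list, genes called higher after inoculation in Yurong1 stood at −0.18 of the change seen in inoculated Guiwei leaves (bootstrap −0.29 to −0.11). Other genes were shifted by −0.28 in this library. Relative to them the value was 0.13 (−0.01 to 0.24, 153 genes with a mean FPKM of at least 5). The genes were called with a spread that included this library, so genes in which it departed from its group entered less often. The low value therefore cannot decide whether it is an inoculated leaf under the wrong label. On a scale from Guiwei (0) to Yurong1 the library lay at 0, with the same limit on the genes used. On the first principal component, over all genes tested, it lay at −77.8, and the Yurong1 libraries at 46.5 to 58.4. That argues against a Yurong1 leaf. Heat shock transcripts that only took reads from other genes would shift these alike. Scaled per library, the differences of other genes spread 2.51 times as widely as between the other 2 mock libraries (SD of 0.65 and 0.3 before this scaling). That argues against lost reads as the whole cause. Heat or handling of that tree or sample may be involved, and no biological explanation was tested.

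More genes were called in Yurong1 (586) than in Guiwei (176). A wider spread among Guiwei libraries was tested by a fit without one of them. Without Guiwei mock replicate 2, where the median residual SD in Guiwei fell from 0.238 to 0.166 (0.167 in Yurong1), 223 genes were called in Guiwei and 1815 in Yurong1, which argues against spread as the cause. With 1 Yurong1 mock library left out as well, the counts were 203 and 1700, 99 and 755, or 131 and 645. Depth would need larger totals in Yurong1, which were 0.89 of those in Guiwei. A larger response in Yurong1 stays open. Genes called in Guiwei changed in Yurong1 by a median share of 0.64, and genes called in Yurong1 changed in Guiwei by 0.34. The ratio was 1.87 (1.29 to 2.87 without single libraries). The lists held 176 and 586 genes, and a shorter list of stronger genes can give a larger share by itself. The ratio therefore cannot decide whether the response was larger in Yurong1.

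Genes with a mean FPKM of at least 5 in one cultivar and below 0.5 in every library of the other numbered 93 for Yurong1 and 68 for Guiwei. Of those with LITCHI identifiers 28.3% had a neighbouring identifier expressed in the same cultivar alone, against at most 5.3% in 1000 random draws. Runs were short, since only 2 reached 3 identifiers and the longest held 3. This is consistent with segments that one cultivar lacks or that the reads of one cultivar do not match in the reference, and shared regulation of neighbours stays open. Whether identifiers follow genome order is not stated in the sources used here. Totals that differed by at most 1.29 times argue against depth.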

How the results depend on the processing

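Chosen after the data were seen were voom, library weights gene by gene, the fit with only replicate 3 of the Guiwei mock libraries, and the fit without heat shock genes. Of 3072 alternatives of the 101 named calls, 2412 stayed called in the same direction, 660 lost the call and 0 turned. Of 414 alternatives of the 23 called lists, 334 stayed called, 79 lost the call and 1 turned, the heat shock list in Guiwei without Guiwei mock replicate 2 (adjusted p = 0.193, higher; 1.48e-07 to 0.193 over the left-out libraries). Counts follow in the order Guiwei response, Yurong1 response, difference of responses, mock leaves and inoculated leaves, and those within 1.5 times the values above are left out. Leaving out each library gave 40 to 236, 113 to 1815, 0 to 12, 4261 to 6326 and 3196 to 5763 genes, an agreement of the responses of 0.32 to 0.47, and 3 to 9, 5 to 9, 5 to 11, 1 to 7 and 0 to 0 lists. Without a filter 111 genes were called in Guiwei and 7 for the difference. The stricter filter, which tests fewer genes, gave 84, 256, 1, 3408 and 2063 genes. Median-of-ratios scaling gave 270, 1028 and 12, quantile normalization 907 in Yurong1 and 11 for the difference, rescaling to a common sum 0 and eBayes without trend 5 for the difference. Library weights gave 10103, 3825, 4420, 12783 and 8742 genes, but did not converge (weights from 0.09 to 39.22), and gene by gene 1977, 3207, 889, 9368 and 7650. Fits to the compared groups alone gave 3 and 1243, and for the difference they are the fit already made. The replicate block gave 94 in Guiwei, 435 in Yurong1 and 0 for the difference, and within cultivar 1, 347 and 0, although numbers did not pair: same-number libraries correlated at −0.27 to 0.24 in their deviations, and 3 of 12 did so best with their own number. A 2-fold threshold gave 320 in Yurong1, 2700 and 2090 between the cultivars, and an adjusted p below 0.01 gave 13, 102, 0, 3506 and 2662. Voom gave 0 for the difference (2246 at an unadjusted p below 0.05 in limma) and an agreement of 0.46. Only replicate 3 of the Guiwei mock libraries, with its spread taken from the other groups, gave 37, 1486, 5 and 3462. The counts of 6, 6, 8 and 3 lists became 0 each with an estimated correlation, and fry called 0, 2, 0, 10 and 5. Mock leaves gave 5 lists with the stricter filter and 6 with quantile normalization. Apart from fewer genes or libraries, the cause was not tested. At these depths a gene at 0 is bounded only by the floor of 3 reads.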

Other observations

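The tests on words of the descriptions and on NLR genes were chosen after the results were seen, were exact tests (Fisher), and treat genes as independent. The 62 genes called higher after inoculation in both cultivars (22 without Guiwei mock replicate 1 or inoculated replicate 1 of either cultivar, 81 without Guiwei inoculated replicate 3) included metalloendoproteinase 1 (LITCHI017995), cationic peroxidase 1 (LITCHI018055), endochitinase EP3 (LITCHI015508), cell wall invertase (LITCHI030108) and ERF114 (LITCHI020245). The word receptor was held by 12 of the higher genes in Guiwei, where 2.26 were expected (adjusted p = 0.00263), and by 21 in Yurong1 (5.06 expected, 3.91e-05), of 339 genes with the word. Ketoacyl synthases rose in 3 of 8 cases in Yurong1 (0.12 expected, adjusted p = 0.0278). They include LITCHI014914 and LITCHI017426, already counted in the cuticle and wax list, so this adds no separate evidence to that list.

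The NLR list was the only one compared with other genes by its share of calls between the cultivars, and smaller lists held similar shares, such as 5 higher and 3 lower of 12 glutathione S-transferases in mock leaves. Of 197 NLR genes 124 (62.9%) were called in mock leaves, against 32.1% of other genes (odds ratio 3.59, exact p = 1.29e-18), and 119 (60.4%) in inoculated leaves, against 22.6% (5.22, p = 1.48e-29). Among genes near 0 in one cultivar were 8 of the 197 (4.1% against 0.8% of other genes, Fisher's exact p = 0.000323 over all genes tested). Lectin genes were higher in Yurong1 mock leaves in 28 of 64 cases (10.64 expected, adjusted p = 5.77e-05), or 22 without Guiwei mock replicate 2. Pentatricopeptide repeat genes were lower in 79 of 344 cases (48.06 expected, adjusted p = 0.00183) in mock leaves, but in inoculated leaves in 19, fewer than the 34.8 expected. Acid phosphatases were lower in inoculated leaves in 9 of 19 cases (1.92 expected, adjusted p = 0.00751). In mock leaves 8 were lower (2.7 expected, Fisher's exact p = 0.00257, not adjusted over the words tested). Near-identical copies and differences between the cultivars' sequences and the reference were not separated from expression here.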
